A study of Homo sapiens with 3 samples.

How the data were processed

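RNA bound to YBX1, a cold-shock-domain protein that binds mRNA, was studied in T24 cells, an established human bladder carcinoma line. Per the labels' protocols, cells overexpressing Flag-tagged YBX1 were lysed, a portion of the lysate was kept as input, and YBX1 with its RNA was captured on anti-Flag beads. Bound RNA was trimmed on the beads with micrococcal nuclease, released with proteinase K, depleted of ribosomal RNA and sequenced as paired-end reads on an Illumina HiSeq X-Ten. The labels give 3 groups with 1 sample each, namely the RIP input, the YBX1 RIP and the bisulfite-treated YBX1 RIP, in which unmethylated cytosines are converted so that m5C can be read. For the bisulfite sample, the source label names another cell line than the characteristics label, which gives T24; the latter was followed. No group has a replicate.

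The processed data used here are 1 list of YBX1 peaks, and its deposited values are only genome positions: a chromosome, a start and an end for each peak, per the file headers. Trimmomatic and MACS2 are named in the submitters' processing notes, as is build hg19, without versions or settings. The aligner, the peak threshold, the libraries that entered the peak call and any later filter are not given in the sources used here. The last peak on chromosome 1, from 249141761 to 249142478, lies past the end of that chromosome in GRCh38 and inside it in hg19, so the positions are not on GRCh38. Whether positions count from 0 or from 1 is not stated, so coordinates are printed as deposited and a width is the end minus the start. The list holds no peak height, fold, score, p-value, summit, strand, gene name, read count or methylation call. The sequencing depth behind each peak is therefore unknown, and intervals given on shares of peaks (Wilson, 95%) cover counting error only and treat peaks as independent, although neighbouring peaks are not.

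The planned results that need these columns were not computed: peak strength, transcript regions, motifs, m5C sites in peaks, and peaks per gene. No nuclear peak was assigned to a gene, because the gene table at hand is on GRCh38.p14 and coordinates were not converted between builds. The rule for named genes, set before the data were examined, covered the genes with the strongest and the most peaks, the strongest members of 24 fixed gene lists and the genes of the m5C pathway. Of those lists, only the mitochondrially encoded genes could be placed, and 23 lists have no values here. With no peak strength to rank by, every mitochondrial gene was described. Mitochondrial genes were placed with the table's mitochondrial record, on the assumption that the peak list uses that sequence or a version that differs from it by a few bases. The placement was repeated with gene positions shifted by 10 bases in each direction.

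Peaks closer than 5 kb were joined into runs. The share of peaks with a neighbour within 5 kb was compared with 100 random placements of every peak inside its own window of 1 Mb, and of 100 kb. Peaks per chromosome were divided by the number of protein-coding genes that the RefSeq table lists there (20056 in all), taking only each gene's chromosome from the table. Intervals on these rates came from 2000 resamplings of runs within each chromosome. They were set against 10000 random assignments of whole runs to chromosomes in proportion to coding genes. Relations across chromosomes were tested with 100000 permutations, two-sided, and the 6 p-values were adjusted by the Benjamini-Hochberg method. All of these choices were made after the peak list had been seen, apart from counting peaks per chromosome and per gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

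The functions were tested on simulated data. All 500 planted runs of 4 peaks were found. When widths were shuffled within the runs of the 17802 peaks, 10% of 20 simulated lists fell outside the 95% range of the test of run ends. When the widest peak was moved to an end in 20% of runs, 100% were above it. The alternatives tried were merging peaks within 100 bp, other joining distances, narrower sets of peaks, other gene counts and the shift of mitochondrial genes.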

Results

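RNA captured with YBX1 from T24 bladder carcinoma cells was sequenced to locate the regions that YBX1 binds, as the basis for asking which of them carry m5C. Input RNA of the same preparation was sequenced too, but whether it entered the peak call is not given in the sources used here. There was 1 library each of input, YBX1 RIP and bisulfite-treated YBX1 RIP, and no replicates, so the values below describe 1 list of peaks made by the authors, and no spread between cultures can be given. The list contained 17802 peaks covering 11.4 Mb of the hg19 genome. They lay on all 22 autosomes (17288 peaks), the X chromosome (506), the Y chromosome (2) and the mitochondrial chromosome (6). None of them overlapped another. Read depth per peak is unknown.

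Peaks lay over genes of the mitochondrial genome, the only genes to which peaks were assigned. Their placement assumes that the peak list uses the mitochondrial sequence of the gene table, or one that differs from it by a few bases. The samples include no capture from cells without Flag-tagged YBX1, and use of the input in the peak call is unknown. Peaks over these genes therefore cannot be told apart from background capture of abundant RNA. The 2 mitochondrial ribosomal RNAs, RNR1 and RNR2, lay entirely under a single peak, and 10 of the 13 protein-coding genes had at least some bases under a peak. ATP6, a subunit of ATP synthase, was covered over 100% of its length, ND5 over 94.8%, ND4 over 94.6%, ND6 over 86.9% and COX3 over 82.8%. ND4, ND5 and ND6 encode subunits of respiratory complex I and COX3 a subunit of cytochrome c oxidase. Less of the length was covered for ND1 (44.4%), CYTB (40.4%), ND4L (35.4%), COX1 (33.7%) and ATP8 (27.5%). ND2, COX2 and ND3 had no base under a peak.

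Among the 22 mitochondrial tRNAs, TRNV and TRNL1, which flank RNR2, were fully covered. TRNF was covered over 14.1%, which ranged from 0 to 28.2% when gene positions were shifted by 10 bases, so that its overlap is uncertain, and the other 19 had no base under a peak. The peak over the ribosomal RNAs ran from position 638 to 3730 of the mitochondrial chromosome and reached into ND1. A peak at 6181 to 6699 lay in COX1, and 1 at 8516 to 9855 covered parts of ATP8 and COX3 and all of ATP6. The peak at 10662 to 12062 lay over ND4L and ND4, that at 12432 to 14604 over ND5 and ND6, and that at 15240 to 15700 in CYTB. The list gives no strand, so a peak over ND6, which is encoded on the opposite strand to ND5, cannot be assigned to one of these strands. Shifting the gene positions by 10 bases in either direction left the count of coding genes with a peak at 10, while the count of tRNAs with a peak was 2 or 3. The 6 mitochondrial peaks had a median width of 1370 bp, against 470 bp for nuclear peaks. That median was above 99.96% of the medians of 10000 random sets of 6 peaks from the list, a description of these libraries and not a test between conditions. The random sets were not matched for exon length or RNA level. The percentile therefore cannot be ascribed to YBX1 binding.

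**Figure D1:**
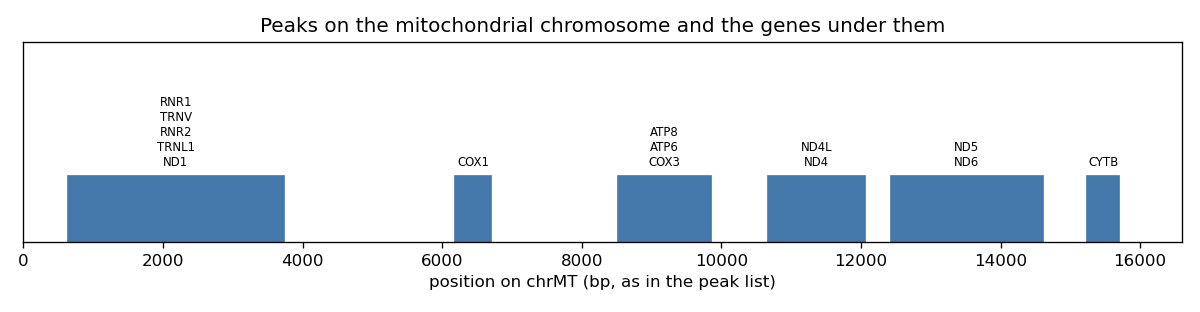
Peaks on the mitochondrial chromosome, drawn to scale as blue bars along the position in base pairs as deposited, with the mitochondrial genes that share more than 20 bases with each peak named above it. The widest of the 6 bars, from 638 to 3730, lies over both ribosomal RNAs, and no bar lies over ND2, COX2 or ND3.

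Most YBX1 peaks were short, and a small number were very wide. The median width was 470 bp, with quartiles of 424 and 631 bp. Of the 17802 peaks, 59.2% (95% Wilson interval 58.4 to 59.9%) were narrower than 500 bp and 9.80% (9.37 to 10.2%) were at least 1000 bp wide. These 1744 wide peaks held 27.7% of all bases under peaks. A group of 49 peaks reached 5000 bp or more.

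The widest peak, of 18.7 kb, lay on chromosome 14 from 105403477 to 105422131. The next, of 18.4 kb, lay on chromosome 11 from 62283311 to 62301702. Peaks of 11.4 kb on chromosome 20 (61273876 to 61285240), 10.9 kb on chromosome 8 (144989230 to 145000179), 10.8 kb on chromosome 15 (42976201 to 42987028) and 10.2 kb on chromosome 16 (88493786 to 88504032) followed. No peak was narrower than 400 bp, and 1138 peaks (6.39%, 6.04 to 6.76%) were exactly this wide. No 2 peaks lay closer than 81 bp.

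Peaks were grouped along the chromosomes. The median gap between neighbouring peaks was 4757 bp, and 12097 peaks (68.0%) had another peak within 5 kb. After every peak was placed at random inside its own 1 Mb window, 25.03% had such a neighbour (24.2 to 25.8% over 100 placements), and after placement inside its own 100 kb window 51.2% (50.6 to 52.0%). The placements used all sequence of a window, transcribed or not. They therefore cannot separate grouping of YBX1 binding from the grouping of genes and exons. Joining peaks within 5 kb gave 8754 separate places, of which 5705 held a single peak, 1512 held 2, 1322 held 3 to 9, and 215 held 10 or more. Those 215 runs contained 18.9% of all peaks.

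The largest run held 50 peaks over 105 kb of chromosome 7, from 98487804 to 98592622. It was followed by 47 peaks over 80.1 kb of chromosome 6 (90362552 to 90442647), 45 over 76.3 kb of the X chromosome (53559740 to 53636055) and 44 over 64.2 kb of chromosome 1 (19464320 to 19528497). Peaks covered 25.7%, 32.7%, 33.8% and 40.7% of these 4 spans. A further run of 35 peaks on chromosome 1 (19400911 to 19455750) ended less than 10 kb before the run of 44. These would be joined at a distance of 10 kb, so the ranking of runs depends on the joining distance. The windows of 1 Mb with the most peaks were that from 64 to 65 Mb on chromosome 14, with 103 peaks, and that from 53 to 54 Mb on the X chromosome, with 102. The median over the 1550 windows with any peak was 6. Wide peaks had a neighbour within 5 kb more often than the others, at 76.4% (74.4 to 78.4%) of 1744 peaks against 67.0% (66.3 to 67.8%) of 16058. This difference of 9.40 percentage points was outside the 95% range of -1.72 to 2.54 points from 1000 shuffles of wide peaks within chromosomes. The shuffles treated peaks as independent, although peaks of a run share their place, so this range may be too narrow.

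**Figure D2:**
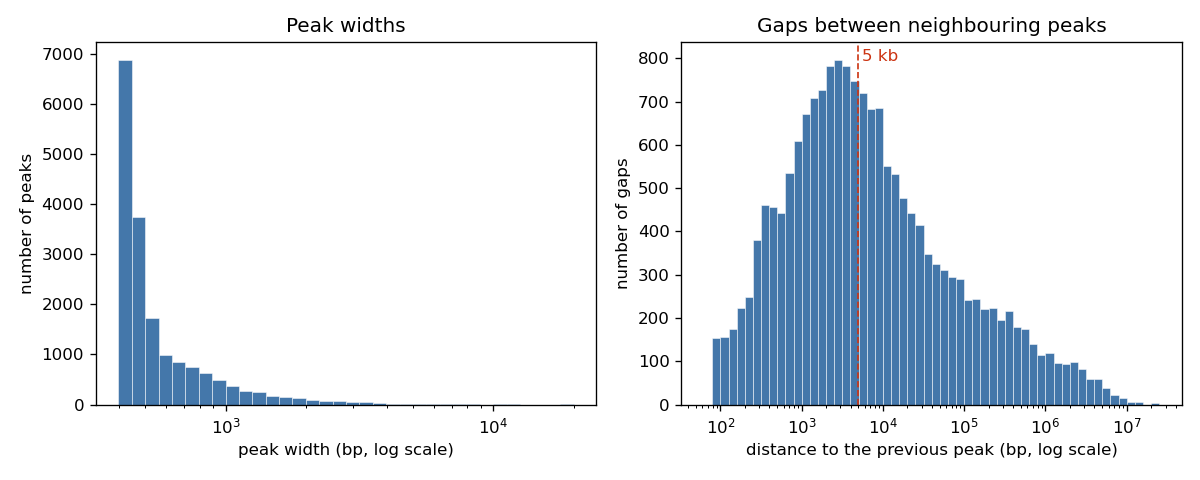
Number of peaks by width in base pairs on a log axis (left), and number of gaps between neighbouring peaks by length in base pairs on a log axis (right), for the 17802 peaks. Widths start at 400 bp, and the dashed line marks the 5 kb within which peaks were joined, close to the median gap of 4757 bp.

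Chromosomes differed in how many peaks they carried for their number of protein-coding genes. Over the autosomes and the X chromosome there were 89.1 peaks per 100 protein-coding genes. Chromosome 22 had the highest rate, 130 (95% interval 108 to 157 from resampled runs), followed by chromosome 21 with 127 (93.3 to 171) and chromosome 15 with 124 (105 to 146). The X chromosome had the lowest rate, 59.7 (46.5 to 75.4), followed by chromosome 5 with 67.7 (58.0 to 78.5) and chromosome 19 with 68.8 (60.0 to 77.9). The intervals of 6 chromosomes (9, 15, 16, 17, 21 and 22) lay above the common rate and those of 5 (3, 5, 11, 19 and X) below it. The other 12 included it.

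The highest rate was 2.18 times the lowest, and 19 of 10000 random assignments of runs to chromosomes by gene number gave a ratio as high. With all genes of the table in place of coding genes, chromosome 17 was highest and chromosome 13 lowest, 2.59 times apart, and with only peaks of at least 500 bp chromosome 16 was highest and chromosome 5 lowest, 2.31 times apart. The intervals describe these libraries and were not adjusted for the 23 chromosomes. Intervals and random assignments both treated runs as independent, although a gene can be split into several runs on its chromosome. The intervals may therefore be too narrow, and the count of 19 too low. A joining distance above 5 kb was not tried for these rates. The Y chromosome carried peaks from 10035856 to 10036680 and from 15638272 to 15638679.

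Across the 23 chromosomes, the number of peaks rose with the number of protein-coding genes (Pearson's r = 0.90, permutation p = 1e-05, adjusted 1.5e-05; Spearman's rho = 0.84, permutation p = 1e-05, adjusted 1.5e-05). The value 1e-05 is the smallest that these permutations can give. Without chromosomes 1 and 21, the farthest from the median gene number, r was 0.80. The number of runs rose with it as well (r = 0.92, rho = 0.91, both with permutation p = 1e-05, adjusted 1.5e-05), and r was 0.86 without chromosomes 1 and 21. The median peak width of a chromosome showed no detectable relation with its peaks per coding gene (r = 0.20, permutation p = 0.367, adjusted 0.441; rho = 0.17, p = 0.445, adjusted 0.445), with r = 0.27 without chromosomes 21 and 22. Chromosomal medians lay between 446.5 bp on chromosome 18 and 490.0 bp on chromosome 16.

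**Figure D3:**
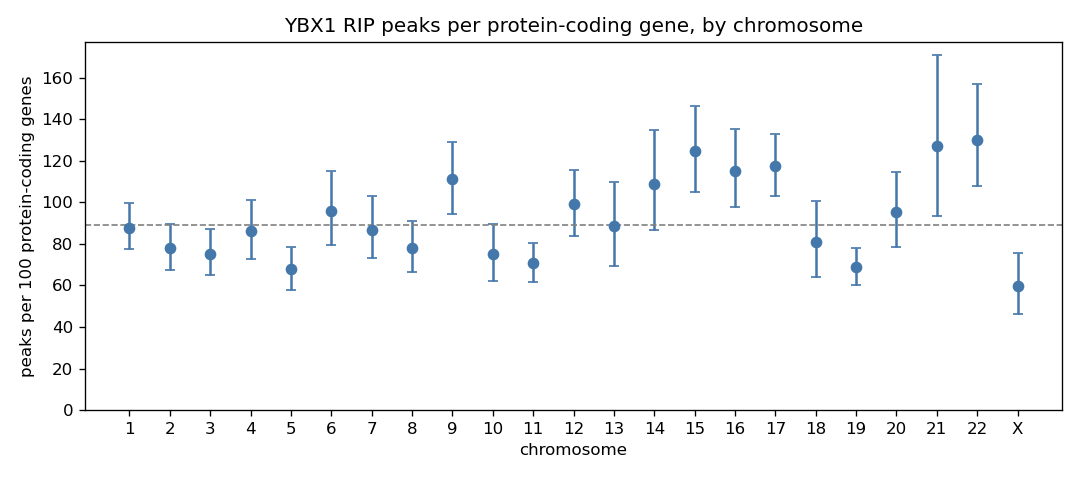
Peaks per 100 protein-coding genes for each autosome and the X chromosome, with points for the rate and bars for the 95% interval from resampled runs; the dashed line is the common rate of 89.1. Chromosome 22 stands highest at 130 and the X chromosome lowest at 59.7.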

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

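Of the 18 alternatives computed, 12 gave a value close to the reported one or on the same side of its range of shuffles, and only merging peaks within 100 bp, which gave 17642 peaks, was chosen before the data were examined. Keeping only peaks of at least 500 bp left 7271. The share of peaks with a neighbour was 50.7% with a joining distance of 2 kb and 77.8% with 10 kb, by construction of the distance. The ratio of the highest to the lowest chromosome was 1.92 without the X chromosome, and between 2.18 and 2.59 under the other alternatives. With all genes of the table as the denominator it was 2.59, with chromosome 17 highest and chromosome 13 lowest, so which chromosomes stand out depends on the gene count used. Requiring at least 50% of the gene under peaks left 5 mitochondrial coding genes. The share of runs with the widest peak at an end was 53.3% with a joining distance of 2 kb, where it was inside the range of shuffles (50.1 to 55.4%), and the cause was not tested. Alternatives set in advance on peak strength, q-value, transcript region, motif windows and methylation coverage were not run, because the list used here has no such column. No paired analysis was possible because each group has 1 sample. With no read counts, the depth below which a bound region would be missed is unknown.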

Other observations

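The tests of peak width were chosen after the widths had been seen. The predictions for the other tests were written before their results, but after the peak list had been looked through. The test of neighbouring transcripts joined in a run was added once the share of runs at each joining distance was known, in place of a first version at 2 kb that decided nothing.

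Within runs, the widest peak lay at an end more often than chance order gives. Over 1537 runs of 3 or more peaks, it was at the first or last place in 50.0% of runs, against 46.6% (44.4 to 48.8%) in 1000 shuffles of widths within runs. In runs of 5 or more peaks the share was 33.6%, against 27.0% (23.8 to 30.2%), and with peaks within 10 kb joined it was 49.1%, against 41.6% (39.4 to 43.8%).

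A candidate explanation is that a terminal exon, often the longest exon of an mRNA and the home of most 3′ UTR sequence, carries a wide peak. It stays open, because its test was the 50.0% share itself, which restates the pattern, and no exon was mapped. A separate neighbouring transcript joined at the end of a run stays open as well. In 525 runs whose largest gap was neither the first nor the last the share was 36.0%, above the 33.7% upper bound of shuffles. Such runs can still hold a joined transcript with several peaks, so this share cannot exclude it. An edge effect that widens both end peaks alike predicted a narrower end peak wider than the range of shuffles. Over 962 runs its geometric mean width was 480 bp, inside the 473 to 483 bp of shuffles, so the prediction was not met. A value inside the range cannot exclude a small effect of this kind. With only peaks within 2 kb joined, the share of 53.3% was inside the range of shuffles, so the pattern depends on the joining distance. The excess over the mean of shuffles was 0.62 percentage points at 2 kb, 3.43 at 5 kb and 7.47 at 10 kb.

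The rate of peaks per coding gene differed between chromosomes by a ratio of 2.18, above the 95th percentile of 1.79 in random assignments, of which 19 of 10000 were as high. Peaks repeated within runs joined at 5 kb do not account for the size of this ratio. With each run counted once the ratio of the highest chromosome, then chromosome 15, to the lowest, the X chromosome, was 2.20. The 95th percentile in random assignments was 1.41. The standing of single chromosomes did change with the count. Chromosome 14 had 108.6 peaks and chromosome 18 had 80.7 per 100 coding genes, but 44.8 and 57.8 runs. A gene split into several runs was still counted more than once, and runs were treated as independent. The percentiles of random assignments given here, and the count of 19, may therefore be too low. Gene families that most cell types do not express, such as olfactory receptors and keratin-associated proteins, were removed from the gene count (727 genes). The ratio was then 2.40, from 160 peaks per 100 genes on chromosome 21 to 66.8 on the X chromosome, against a 95th percentile of 1.81. What stays open, untested, is how many copies of each chromosome these cells carry and which other genes they express, since the read counts of the input were not analysed here. The hypothesis that these play a part may be tested with the input reads.

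Peak widths began sharply at 400 bp. The count at this width was 7.28 times the mean count at each of the next 10 widths, and 0% of peaks were narrower than this commonest width. The first value describes the pattern itself, so it cannot favour or exclude an explanation. Lengths of bound fragments with no minimum applied would leave some peaks below the commonest width, and 0% of the 17802 peaks were. This argues against that explanation for this list, although its prediction was written after the widths had been seen. A minimum width set in peak calling or filtering may lie behind the pattern. It stays open, since the settings of the peak call are not given in the sources used here. No biological explanation was tested.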
